A study of Mus musculus with 7 samples.

How the data were processed

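ChIP-seq with an anti-V5 antibody was performed on first and second pharyngeal arches of E10.5 C57BL/6 embryos, and indexed libraries were made with an Illumina TruSeq kit, per the labels' protocols. The groups follow the genotype and library type in the labels: 3 ChIP libraries of arches with V5-tagged MOZ, 3 ChIP libraries of wild-type arches, and 1 input library of tagged arches. No label says whether the replicates came from separate embryos, litters or pools, so p-values measure the spread between these libraries, which may be technical.

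The deposited values are raw read counts per gene, with an Entrez gene identifier and a gene length beside them, per the file headers. The submitters' processing notes name bcl2fastq, featureCounts and MACS and the mouse build mm10, without versions or roles; the aligner, the handling of duplicate reads and the counting options are not given in the sources used here. Peaks were not analysed here. The deposited length of 69.8% of the genes that have a symbol was within 1% of the gene's whole span in RefSeq GRCm38.p6, the assembly that mm10 stands for, so for most genes the counts appear to cover the gene body with its introns. For the other genes the deposited length differs from that span, as for Tbx1, with 5257 bp in a span from 18580979 to 18590671, and the part counted is less certain. Sequence upstream of the gene start is not part of such a span, a ChIP signal at the start of a gene is diluted by the rest of it, and binding between genes leaves no trace in these values. Of genes of at least 3000 bp that lie wholly inside other genes, 77.7% had 0 counts in all 7 libraries, against 0.620% of genes that overlap none, so reads in overlaps were apparently left unassigned and overlapping genes are uncertain. The counts do not separate strands, and members of families with near-identical copies may have lost or shared reads.

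The table has 27179 genes, of which 25275 identifiers matched a symbol in the RefSeq table by gene identifier; coordinates are from that table. No column was left without a sample, and 2632 genes had 0 counts in all libraries. Totals ranged from 806648 to 3488745 counts. No pair of libraries was alike within sampling noise: the chi-square per degree of freedom over genes was 4.17 for the closest pair, V5 replicate 3 and wild-type replicate 3, 10.3 to 11.2 between V5 libraries and 5.15 to 5.79 between wild-type libraries. Each library was therefore counted as 1 replicate. Intervals and floors (3 counts for a gene at 0) cover counting error only, since duplicate reads are not independent molecules.

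V5 and wild-type ChIP libraries were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM factors, glmQLFit with robust estimation, glmQLFTest, two-sided, Benjamini-Hochberg adjustment over 14575 genes, threshold 0.05). TMM factors ranged from 0.923 to 1.04 and the biological coefficient of variation was 0.387. The input did not enter this fit. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are counts divided by the library total and scaled to 1e6. Single genes below the filter and list totals were compared by a two-sided exact permutation test of 3 against 3 libraries, whose smallest p is 0.1.

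Before the data were examined, 22 gene lists were fixed: DLX family, DLX5/6-dependent mandibular genes, arch mesenchyme and neural crest regulators, endothelin pathway, craniofacial signalling, TBX1 and arch artery genes, HOX genes, MOZ complex and MYST acetyltransferases, proliferation and INK4A pathway genes, ribosomal protein genes, mitochondrial respiratory genes, splicing factors, replication-dependent histone genes, immediate early genes, olfactory and vomeronasal receptor genes, keratin-associated protein genes, adult liver and pancreas genes, and markers of blood, endothelial, epithelial, muscle progenitor and neuronal cells. Lists with at least 4 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), with an estimated correlation and with fry beside it. The genes named in the text follow a rule fixed at the same time: genes past the threshold with the largest change or, as none passed, the 5 with the smallest p in each direction; always Kat6a, Dlx1 to Dlx6, Tbx1, Hand2 and Hoxa2; and up to 4 members with the smallest p of each list discussed. Chl1, Dnah11, Erbb4, Tusc3, Dlc1, Msr1, Cdk5rap2 and the Skint genes fall outside this rule and were chosen after their values were seen, as was the division of genes by length.

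ChIP libraries were set against the input as the log2 ratio of mean CPM with a prior count of 0.5, over genes with at least 70 counts in all. List medians were placed among 10000 random lists matched on input level. The correlation between both ratios was compared with 20 simulated data sets without any effect, in which every library, the input included, had the common dispersion of the ChIP fit.

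The gene-level and list tests were checked on simulated counts drawn from the real means and library sizes, with a dispersion trend shared by both groups. For the gene-level test 200 genes were changed by 2, 4 or 8-fold in each of 3 draws over 14575 genes. The quasi-likelihood test made 333 calls, of which 21 were false. Alternatives were DESeq2 1.42.0 (test and size factors), edgeR's likelihood ratio test, limma-voom with and without library weights, other filters and scalings, removal of a trend on gene length, the replicate number as a block, sets of genes left out, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.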

Results

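Anti-V5 chromatin immunoprecipitation and sequencing (ChIP-seq) was used to map MOZ, also called KAT6A, a histone lysine acetyltransferase of the MYST family, in the first and second pharyngeal arches of C57BL/6 mouse embryos at E10.5, the tissue that forms the jaws, the middle ear and parts of the neck. The tagged embryos carried a Flag-V5-BIO tag at the C-terminus of both copies of MOZ. Arches of wild-type embryos, which have no V5 epitope, went through the same immunoprecipitation as the negative control. There were 3 ChIP libraries from tagged arches (V5 libraries), 3 from wild-type arches, and 1 input library, which is chromatin of tagged arches without immunoprecipitation. The deposited values are read counts for 27179 genes, taken over the whole span of most of them as far as the deposited gene lengths show, so introns were mostly included and reads between genes were not seen.

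The V5 libraries held 806648, 1138431 and 3286602 counts for replicates 1, 2 and 3, and the wild-type libraries held 1288732, 1327452 and 2504595. The input held 3488745. At these depths a gene with 0 counts could still have had up to 3.72 CPM (counts per 1e6 counts of the library) in V5 replicate 1 and 0.913 in V5 replicate 3, from counting error alone. A single gene, Chl1, took 2.12% to 3.51% of the counts of the ChIP libraries and 5.97% of the input. Wild-type replicate 2 differed from the other libraries in the sex chromosomes, with 2.77% of its counts in genes of chromosome X (3.94% to 4.51% in the other 6 libraries) and 0.0503% in genes of chromosome Y (0.0101% to 0.0314%).

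The first comparison asks where tagged MOZ was enriched, and sets the V5 libraries against the wild-type libraries gene by gene. No gene passed after correction for the number of genes tested. Of 14575 genes with enough counts, 0 were higher and 0 lower in V5 with edgeR's quasi-likelihood test at an adjusted p of 0.05, and the smallest adjusted p was 0.980. At an unadjusted p under 0.05 there were 600 genes, fewer than the 729 that chance gives, and 399 of them (66.5%) had more reads in V5. That lean was lost with limma-voom (49.2% of 378 genes) and without V5 replicate 3 (53.5% of 1610 genes). DESeq2 also called 0 genes, with 1048 of 24447 genes at an unadjusted p under 0.05. Its smallest adjusted p was 0.0624, for Rrp9, close to the threshold. With edgeR's likelihood ratio test, which called 0 genes too, Rrp9 had an adjusted p of 0.0640, and Zfp36l2 and Actr5 had 0.0864. Meanwhile limma-voom called 1 gene, Sgcz, as lower. The 3 V5 values lay wholly above the 3 wild-type values in 701 genes and wholly below in 783, together 10.2% of the tested genes, where chance gives 10%. With simulated changes added to counts of these means and depths, the test recovered 17.4% of genes changed 2-fold, 57.2% of those changed 4-fold and 81.8% of those changed 8-fold. A 2-fold enrichment over a whole gene would thus mostly not be detectable at this depth and spread. The simulation gave both groups the same spread, whereas V5 libraries varied more than wild-type libraries, so these rates may be too high for the real data.

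The 5 genes with the smallest p among those with more reads in V5 were Rrp9, Zfp36l2, Actr5, Dtx3l and Kmt2d, none of which passed. Kmt2d, a histone H3 lysine 4 methyltransferase (GeneID 381022, chromosome 15, 98831669 to 98874077 in mm10), had 67.0 ± 21.8 CPM in V5 and 23.8 ± 0.950 in wild type (SD, n = 3), with 29.0 in the input. Its log2 fold change was 1.52 (SE 0.41, edgeR adjusted p = 0.980). Rrp9, a protein of the small nucleolar particle that processes ribosomal RNA (GeneID 27966, chromosome 9, 106477309 to 106485415), had the smallest p of all genes, with 69, 17 and 34 counts in V5 replicates 1 to 3, 4, 2 and 7 in wild type, and 31 in the input. That is a log2 fold change of 3.89 (SE 0.85), which was 2.28 without V5 replicate 1. Zfp36l2, an RNA-binding protein that promotes mRNA decay (chromosome 17, 84183924 to 84187947), had a log2 fold change of 2.70 (SE 0.63), with 43, 70 and 46 counts against 7, 9 and 19. Actr5, a subunit of the INO80 chromatin remodeller, stood at 2.85 (SE 0.68) and Dtx3l, a ubiquitin ligase, at 3.24 (SE 0.87). Without wild-type replicate 3 Actr5 stood at 3.68, and without V5 replicate 1 Dtx3l stood at 2.60. In all 5 of these genes every V5 library lay above every wild-type library in CPM, a separation that their choice by smallest p favours. The single input was also above every wild-type library in all 5, with 8.89 CPM in Rrp9, 15.8 in Zfp36l2, 20.9 in Actr5 and 9.75 in Dtx3l. V5 replicate 3 lay below the input in Zfp36l2 and Actr5, and above it in Rrp9, Dtx3l and Kmt2d. Low wild-type values thus contribute to these differences. Without any filter on low counts, 9 genes were higher in V5 at an adjusted p under 0.05, Rrp9 and Zfp36l2 among them, and leaving out V5 replicate 2 gave 2 genes, Chl1 and Rrp9.

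In the other direction the 5 genes with the smallest p were Sgcz, Setd5, Zup1, Gm6213 and Gm12814, and they did not pass either. Sgcz, which encodes zeta-sarcoglycan and is among the longest genes here (chromosome 8, 37517840 to 38661705), had 1011 ± 101 CPM in V5 and 1350 ± 148 in wild type (SD, n = 3), a log2 fold change of -0.39 (SE 0.11, edgeR adjusted p = 0.980). The input had 1092 CPM. Setd5, a SET-domain protein of chromatin (chromosome 6, 113077262 to 113153432), stood at -1.03 (SE 0.30) with 56.6 ± 20.1 against 119 ± 24.3 CPM and 59.9 in the input. Zup1, a deubiquitinase, stood at -1.83 (SE 0.54), and at -2.56 without V5 replicate 3. The predicted genes Gm6213 and Gm12814 stood at -1.11 (SE 0.33) and -2.08 (SE 0.63); Gm12814 is annotated as a pseudogene and lies among the Skint genes of chromosome 4, and such copies can lose or gain reads from their relatives.

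**Figure D1:**
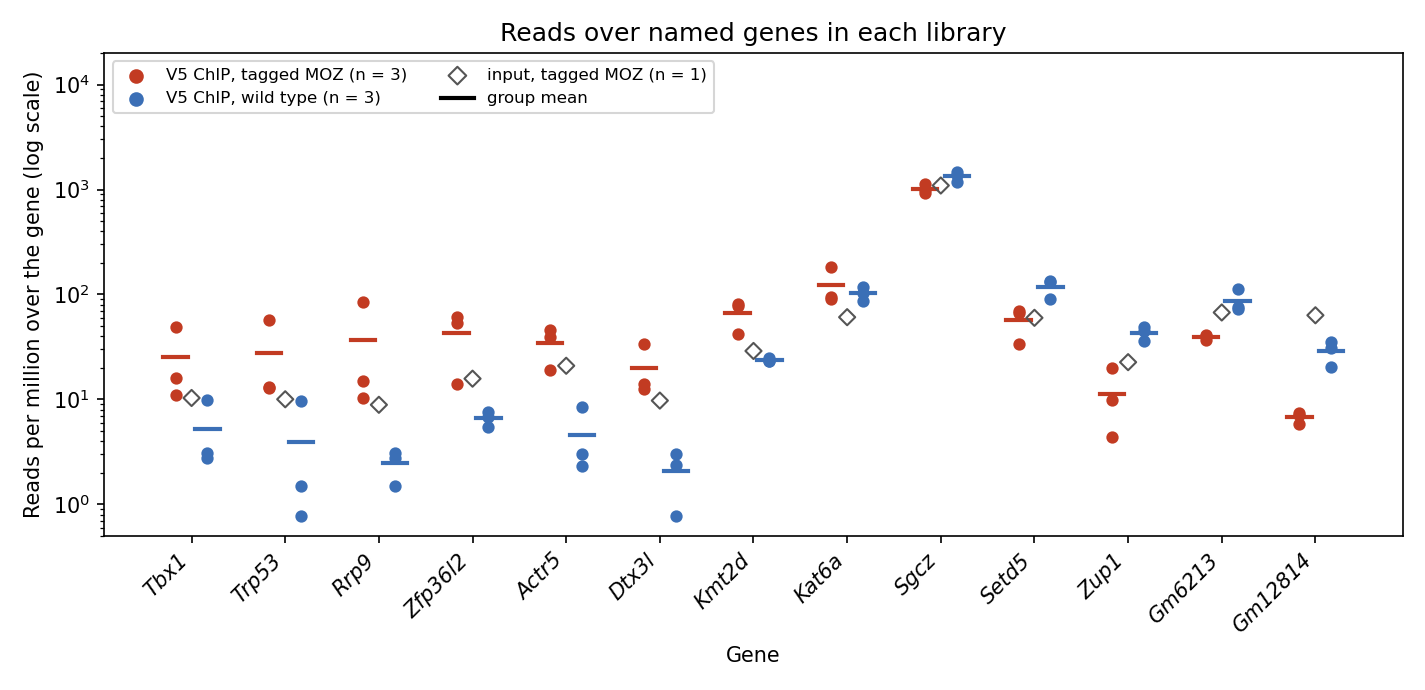
CPM (log scale) over 13 named genes in each ChIP library, with tagged-MOZ libraries in red, wild-type libraries in blue, bars at the group means and the single input as open diamonds. In the 5 genes from Rrp9 to Kmt2d all red points lie above all blue points, from Sgcz to Gm12814 all lie below, and in Kat6a they overlap; none of these genes passed the test over all genes.

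A set of genes fixed before the data were examined held Kat6a itself and transcription factor genes with known roles in the arches. Tbx1, a T-box transcription factor of the pharyngeal apparatus (GeneID 21380, chromosome 16, 18580979 to 18590671), had 13, 56 and 36 counts in the V5 libraries, 4, 13 and 7 in the wild-type libraries and 36 in the input. Its mean was 25.4 ± 20.7 CPM in V5 and 5.23 ± 3.95 in wild type (SD, n = 3). The log2 fold change of 2.31 (SE 0.77) did not pass over all genes (edgeR adjusted p = 0.980), nor when adjusted over the list alone (adjusted p = 0.0870). It was 1.41 without V5 replicate 2 and 3.09 without wild-type replicate 2. Every V5 library lay above every wild-type library, although the input, at 10.3 CPM, was also above all of the wild-type libraries and close to V5 replicate 3. Kat6a itself (chromosome 8, 22859442 to 22943259), the locus that carries the tag, had 73, 207 and 313 counts in V5 and 133, 155 and 218 in wild type, a log2 fold change of 0.28 (SE 0.28, edgeR adjusted p = 0.982). V5 replicate 2 decided its direction, since without that library the value was -0.10.

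The Dlx genes, homeobox genes that set the identity of the lower and upper jaw, had too few counts for the gene-level test. Together the 6 Dlx genes held 41, 43 and 50 counts in the V5 libraries and 15, 24 and 34 in the wild-type libraries, or 50.8, 37.8 and 15.2 CPM against 11.6, 18.1 and 13.6. The ratio of the group means was 2.40, with a two-sided exact permutation p of 0.2, and 0.1 is the smallest p that 3 against 3 allow. V5 replicate 3, the deepest of the ChIP libraries, lay inside the wild-type range. Dlx3 (chromosome 11, 95120117 to 95125296) had 2, 18 and 12 counts against 3, 1 and 4, a ratio of mean CPM of 4.69 (exact permutation p = 0.1). On the log2 scale that ratio is 2.23, and it was 0.98 without V5 replicate 2. Dlx2 (chromosome 2, 71543408 to 71546754) had 10, 18 and 11 against 1, 5 and 13, a ratio of 3.24 (exact permutation p = 0.3), and Dlx5 had 27, 7 and 10 against 1, 10 and 10, a ratio of 3.47 (exact permutation p = 0.5). On the log2 scale the Dlx5 ratio is 1.79, and it was 0.16 without V5 replicate 1 and 2.58 without wild-type replicate 2. Dlx4 had 2, 0 and 15 counts against 10, 5 and 4. Dlx1 overlaps an antisense gene and had 0, 0 and 2 counts against 0, 3 and 3. Dlx6 lies wholly inside other genes and had 0 counts in every library, as did most genes placed in this way. Hand2, a transcription factor downstream of endothelin in the lower jaw, had 2, 1 and 17 counts against 1, 6 and 4, and Hoxa2, the selector gene of the second arch, had 1, 1 and 16 against 5, 1 and 8.

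Among the gene lists fixed in advance, 1 of the 19 that could be tested passed, the list of cell cycle and INK4A pathway genes, and only with a preset correlation. Of its 16 tested members 12 had a positive log2 fold change, with a median of 0.66, and the list passed limma's camera test with a preset correlation of 0.01 (adjusted p = 0.0279). With an estimated correlation the call was lost (adjusted p = 0.811), and fry, which asks whether the genes of a list move one way on balance, did not pass (adjusted p = 0.430). Trp53, the p53 tumour suppressor, had 46, 15 and 42 counts in V5 and 1, 2 and 24 in wild type, a log2 fold change of 2.69 (SE 0.86). Cdc6, which loads the replicative helicase, stood at 1.55 (SE 0.74), cyclin A2 (Ccna2) at 1.63 (SE 0.85) and the helicase subunit Mcm5 at 1.34 (SE 0.77). No member passed over all genes or adjusted over the list alone. The total over the list was 542 ± 123 CPM in V5 and 402 ± 60.2 in wild type (SD, n = 3, exact permutation p = 0.2), and the libraries of the groups overlapped. The call ended without V5 replicate 1 (adjusted p = 0.423) and without wild-type replicate 1 (adjusted p = 0.0710). In simulated data a true 1.5-fold shift of a list of 23 genes was found in 20 of 20 draws with the preset correlation, at the price of a false list in 5 draws, and in 7 of 20 draws with an estimated one.

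The lists closest to the arches did not pass. Of 23 tested regulators of arch mesenchyme and neural crest, 17 had a positive log2 fold change, with a median of 0.23 (camera adjusted p = 0.152); the largest differences by p were in the forkhead gene Foxc2, at 2.07 (SE 0.92), and Pax9, a paired-box gene of the pharyngeal pouches and jaw mesenchyme, at 1.31 (SE 0.60). Leaving out V5 replicate 3 brought this list past the threshold, so that 2 lists passed. The TBX1 and arch artery list had 9 of 13 members positive (adjusted p = 0.714), with Fgf10 at -0.59 (SE 0.28) beside Tbx1. In the craniofacial signalling list 15 of 25 were positive (adjusted p = 1.00), with the receptor gene Fgfr1 at 0.97 (SE 0.41) and the Wnt co-receptor gene Lrp6 at -0.59 (SE 0.28). The endothelin pathway list had 3 of 7 positive (adjusted p = 1.00), its mean and median having opposite signs at 0.07 and -0.04. The list of genes that depend on Dlx5 and Dlx6 in the lower jaw had 3 of 5 positive (adjusted p = 0.874), with Plagl1 at 1.05 (SE 0.47). In the HOX list 4 of 6 were positive (adjusted p = 0.801), and Hoxd3 led with 0.88 (SE 0.55) although it overlaps other genes. None of these lists had a member that passed adjusted over the list alone, and all of them stayed above the threshold with an estimated correlation.

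Genes of the MOZ complex and of other MYST acetyltransferases had 632, 629 and 629 CPM in the V5 libraries and 567, 566 and 607 in the wild-type libraries, a ratio of 1.09 with no overlap between the groups (exact permutation p = 0.1). Of the 13 tested, 10 had a positive log2 fold change (camera adjusted p = 0.667), and Brd1, a scaffold of a related acetyltransferase complex, led with 0.85 (SE 0.38).

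**Figure D2:**
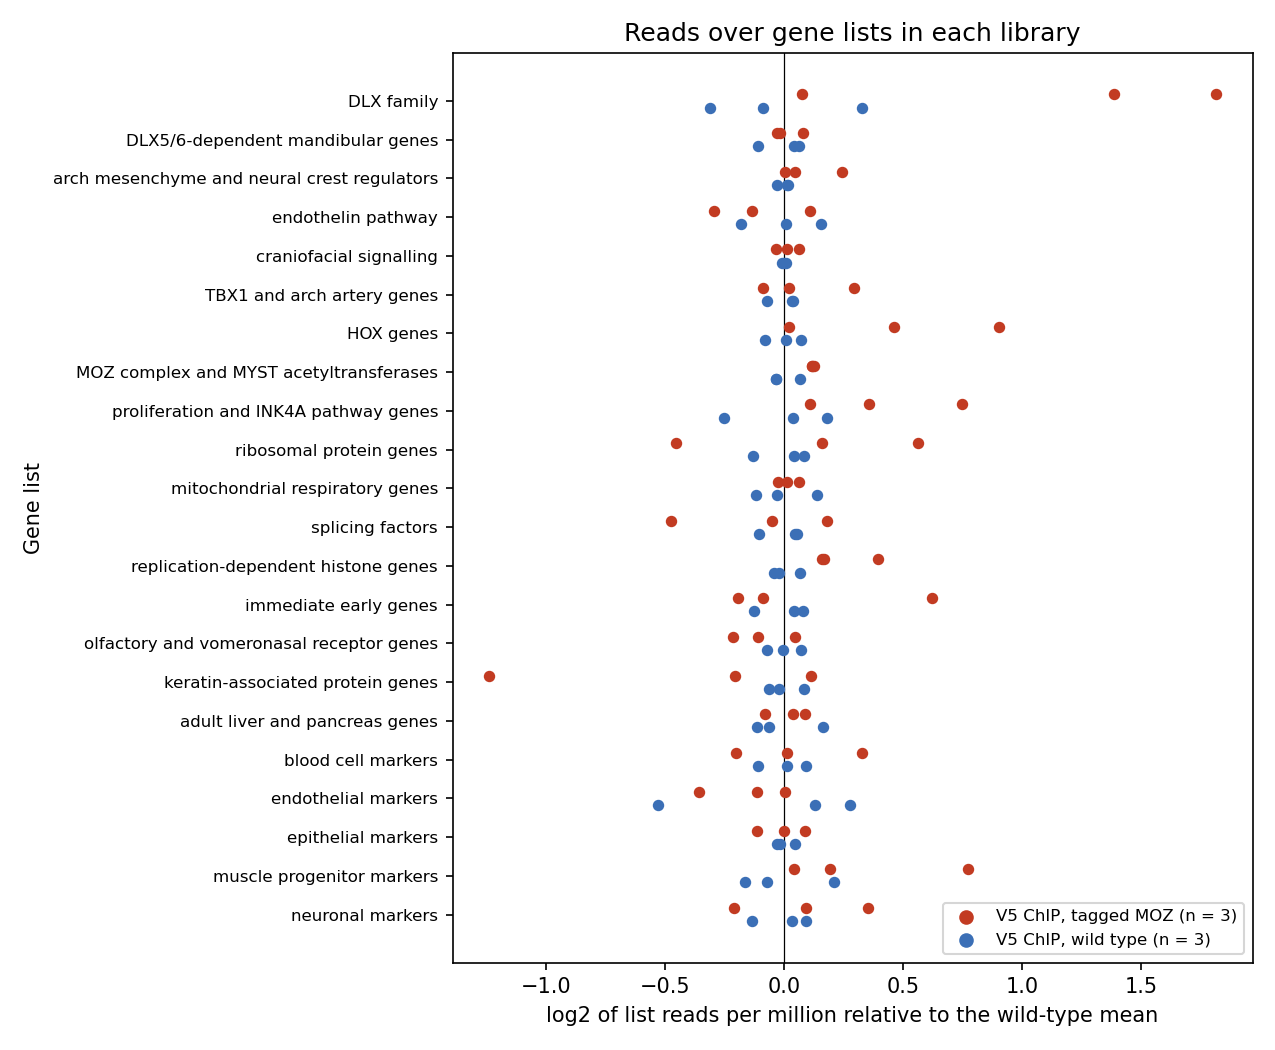
Reads over each of the 22 gene lists in each ChIP library, as log2 of the list's CPM relative to the mean of the wild-type libraries, with tagged-MOZ libraries in red and wild-type libraries in blue. The red points scatter more widely than the blue ones in most lists, and the MOZ complex and histone lists are the ones whose 3 red points all lie above the 3 blue ones.

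Broadly expressed genes, silent genes and markers of other cell types served as comparison groups, and none of them passed. Olfactory and vomeronasal receptor genes, which are silent in this tissue, had 66 of 145 tested members positive and a median of -0.12 (camera adjusted p = 0.152); as a large family with near-identical copies their counts are uncertain. Ribosomal protein genes had 5 of 7 positive (adjusted p = 0.841), mitochondrial respiratory genes 16 of 33 (adjusted p = 0.874) and splicing factors 15 of 31 (adjusted p = 0.714), with Sf3a3 at 1.67 (SE 0.63). Endothelial markers had 6 of 11 positive (adjusted p = 0.801), with the receptor gene Tie1 at 2.13 (SE 0.71). Epithelial markers had 6 of 8 positive and muscle progenitor markers 3 of 4, with adjusted p values of 0.667 and 0.714. Blood cell markers had 6 of 10 positive (adjusted p = 0.841), neuronal markers 4 of 9 (adjusted p = 0.953), adult liver and pancreas genes 7 of 12 (adjusted p = 0.944) and immediate early genes 2 of 4 (adjusted p = 0.667). In the mitochondrial, neuronal and adult liver lists the median, the mean and the camera direction did not share a sign. Replication-dependent histone genes had 2 tested members and keratin-associated protein genes 0, so they have only totals, 129 ± 12.4 against 109 ± 4.41 CPM for the histone genes (exact permutation p = 0.1) and 41.7 ± 17.7 against 52.7 ± 2.80 CPM for the keratin-associated genes (SD, n = 3, exact permutation p = 0.5). Over the read totals of the 22 lists the smallest exact permutation p was 0.1, and 0.880 after Benjamini-Hochberg adjustment.

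The summed reads of short genes were a larger share in V5, in a comparison chosen after the data were seen. Chl1 and Cdk5rap2 were left out of these sums. Reads in autosomal genes of 1 to 10 kb, divided by reads in genes over 100 kb, were 1.19 times the wild-type mean in the V5 libraries (SD 0.0912, n = 3), with 1.14, 1.29 and 1.13 in replicates 1 to 3 and 0.991 to 1.01 in the wild-type libraries. All 3 V5 libraries were higher than all 3 wild-type libraries, and the two-sided exact permutation p of 0.1 is the smallest this design allows. Without the 200 short genes of highest mean share the ratio was 1.13 (SD 0.103) and the groups stayed apart. Without the 200 of highest share in any one library it was 1.10 (SD 0.0963) and the groups overlapped, with V5 replicate 1 at 0.991, below every wild-type library (exact permutation p = 0.4). The latter choice takes out high values of the most variable libraries. It lowered the short gene counts from 25458 to 20834 in V5 replicate 1 and from 36350 to 34067 in wild-type replicate 1, so this overlap is partly built in. From 1 kb up the ratio fell with gene length, from 1.24 at 1 to 3 kb through 1.18 at 3 to 10 kb and 1.07 at 10 to 30 kb to 1.04 at 30 to 100 kb. Genes of up to 1 kb were at 1.02 (SD 0.0864) and the groups overlapped (exact permutation p = 0.9). Among short genes, protein-coding genes outside the receptor families were at 1.22 (SD 0.101), while short olfactory and vomeronasal receptor genes were at 1.02 (SD 0.0816) and overlapped the wild-type range. The V5 share was close to the input's, at 0.976 of it (SD 0.0750), and the wild-type share was 0.823 of it (SD 0.00744).

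**Figure D3:**
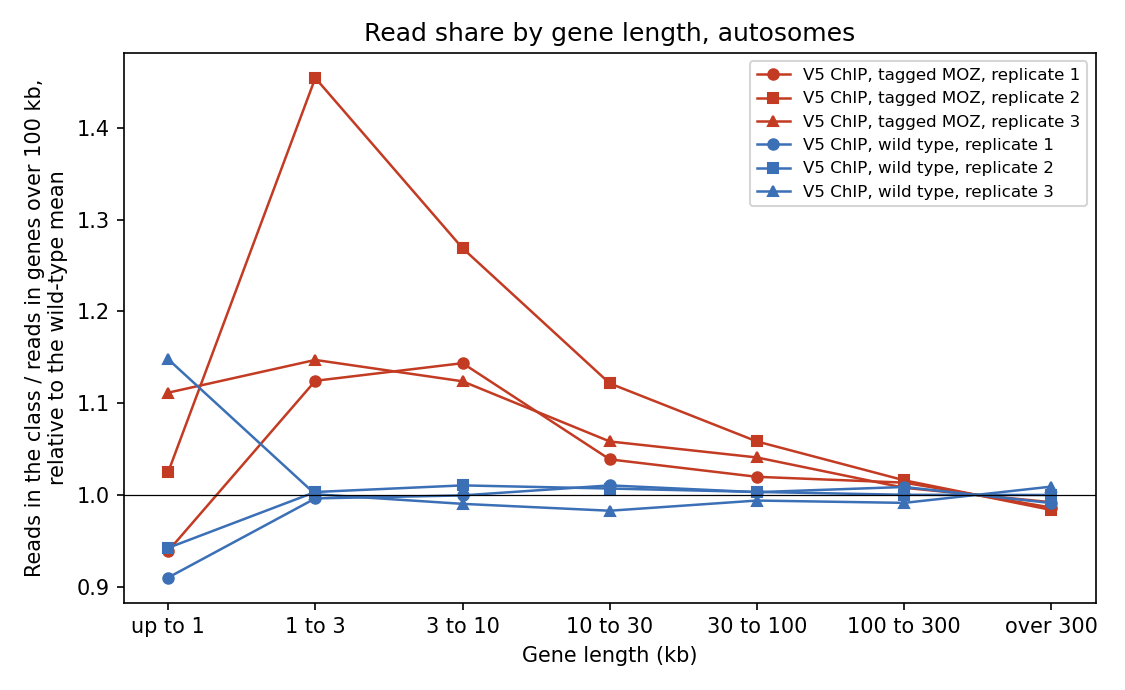
Reads in autosomal genes of each length class (kb) in each ChIP library (tagged MOZ in red, wild type in blue). Values are divided by reads in genes over 100 kb and by the wild-type mean of that ratio. Chl1 and Cdk5rap2 were left out. From 1 to 100 kb the 3 red lines lie above the 3 blue lines, furthest in V5 replicate 2 at 1 to 3 kb, while for genes of up to 1 kb the lines overlap.

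The second comparison sets each ChIP group against the input, which has no replicate, so these ratios describe the libraries and carry no test. Cell cycle and INK4A pathway genes were above the input in the V5 libraries, with list medians of 0.35, 0.20 and 0.13 on the log2 scale for replicates 1 to 3, and below it in the wild-type libraries, with -0.74, -0.33 and -0.17. For the ratio of group means, the median of that list was 0.61 for V5 and -0.46 for wild type. These lay at the 99.5th and 0.780th percentile of 10000 random lists matched on input level. Some other lists were as extreme in both groups. Craniofacial signalling genes were at 99.8 for V5 and 99.3 for wild type, ribosomal protein genes at 0.330 and 0.470. The V5 value of 0.61 lay above the list median of every V5 library, so this measure overstates the single libraries. It moved with each V5 library left out, to 0.35 without replicate 1, 0.29 without replicate 2 and 0.85 without replicate 3. Arch mesenchyme and neural crest regulators had medians of 0.44, 0.56 and 0.41 in the V5 libraries and 0.36, 0.26 and 0.18 in the wild-type libraries. By the ratio of group means their medians were 0.52 for V5 and 0.12 for wild type, at percentiles of 99.95 and 83.4. This list was thus extreme in V5 alone. The value of 0.12 lay below the list median of every wild-type library, so this measure overstates the gap. For the ratio of group means, craniofacial signalling genes were above the input in both groups, with medians of 0.42 for V5 and 0.31 for wild type. Their medians in single V5 libraries were lower, at 0.27, 0.40 and 0.19. By the same ratio ribosomal protein genes were below the input in both groups, at -0.42 and -0.37. The V5 median of the craniofacial list was 0.28 without V5 replicate 2, and that of the ribosomal list was -0.90 without V5 replicate 3, its medians in single V5 libraries being -2.17, -0.46 and -0.26. Across 16736 genes, the log2 ratios of both groups to the input correlated at 0.595, but they share that input, and simulated libraries with no effect at all gave 0.733. The covariance was 0.330 against 0.372 in the simulation, so the observed value was no higher than that of libraries with a common input and the spread assumed for it. Without V5 replicate 3 the correlation was 0.434.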

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

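Leaving out genes of chromosomes X and Y and the mitochondrion, Chl1 and Cdk5rap2, genes over 30 kb or both V5 replicates 1 and 2, library weights, list totals and all settings of the short gene share were chosen after the data were seen. The count of 0 genes higher and 0 lower held with DESeq2, the likelihood ratio test, 3 other scalings, 2 other filters, no robust estimation and the input in the fit. It also held with the length trend removed, without sex chromosome and mitochondrial genes, without Chl1 and Cdk5rap2 and among genes of 30 kb or shorter. Unadjusted p under 0.05 was met by 314 to 1048 genes in these fits, which differed in the number of genes tested. The lowest count was 314 of 7248 genes of 30 kb or shorter and the highest 1048 of 24447 genes with DESeq2. limma-voom called 1 gene lower (Sgcz), no filter 9 higher, library weights 4 lower (Erbb4, Skint3, Sgcz, Skint4), and leaving out both V5 replicates 1 and 2 gave 1 higher (Chl1) and 4 lower (Skint3, Skint4, Skint5, Skint6), with the single V5 library assumed to vary like the others. Leaving out 1 library gave 0 to 2 genes higher (2 without V5 replicate 2, 1, Dnah11, without V5 replicate 3) and 0 lower. The cause of these calls was not tested. The share of genes at an unadjusted p under 0.05 that were higher in V5 was 66.5%, but 49.2% with limma-voom, 53.5% without V5 replicate 3, 22.4% without both V5 replicates 1 and 2, and, with the replicate block, 51.3%, or 47.4% with the length trend removed as well. Kat6a ranged from -0.10 without V5 replicate 2 to 0.47 without V5 replicate 3, and was -0.15 without both V5 replicates 1 and 2; V5 replicate 2 had the highest Kat6a value of the 6 libraries, 182 CPM.

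The list of cell cycle and INK4A pathway genes lost its call with an estimated correlation (adjusted p 0.811), with fry (0.430) and without both V5 replicates 1 and 2 (0.713), when 0 lists passed, as 0 did with exact tests of list totals. Over single libraries left out its adjusted p ranged from 0.00213 to 0.423 and the lists passing from 0 to 2; it was lost without V5 replicate 1 (0.423) and wild-type replicate 1 (0.0710), and 2 lists passed without V5 replicate 3. The cause was not tested. No label says whether libraries of the same replicate number share a litter, day or batch. Deviations of same-numbered libraries correlated at 0.0121, -0.00208 and 0.0456, and not every library correlated best with its own number. Thinned to 800000 reads, V5 replicate 3 and wild-type replicate 3 differed by a chi-square per degree of freedom of 1.93, against 3.20 to 3.49 between wild-type libraries. They are also the 2 deepest ChIP libraries, with the fewest genes at 0 after thinning (5526 and 5689). Their closeness is thus not specific to a batch, and a shared batch for that number stays open. With the replicate number as a block, and with the length trend removed as well, 1 gene was higher (GeneID 100861531, without a symbol) and 0 lower. With the block alone the cell cycle list had an adjusted p of 0.0248. Lists were not run with the length trend removed, alone or with the block. The call was thus not checked against the larger share of short genes in V5. The 4 members with the smallest p are 7132 to 18912 bp long, against a median of 30217 bp over tested genes. The correlation of V5 and wild-type ratios to the input ranged from 0.434 without V5 replicate 3 to 0.603, and the short gene share from 1.10 to 1.22. Depth limits the gene-level test: among simulated 4-fold changes 87.9% were found at a mean count of at least 50 and 57.2% over all.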

Other observations

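All tests of this part were chosen after the results were seen, except those on other splits of the libraries.

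Some neighbouring genes and single libraries stood apart without passing the gene-level test. Sgcz, Tusc3 and Gm6213, neighbours on chromosome 8 between 37517840 and 39368268, had log2 fold changes of V5 over wild type of -0.39, -0.36 and -1.11, while the genes on either side, Dlc1 and Msr1, stood at -0.01 and -0.17. Kat6a, which carries the tag, lies on the same chromosome at 22859442 to 22943259. Dnah11, an axonemal dynein gene on chromosome 12, had 2152 counts in V5 replicate 2 and 594 in V5 replicate 1, against 321 and 428 in the wild-type replicates 1 and 2 of similar depth. HOX genes held 217, 294 and 160 CPM in V5 replicates 1 to 3 and 165, 158 and 149 in the wild-type libraries (exact permutation p = 0.2).

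Short genes held 1.19 times the wild-type share of reads in V5. A bias toward gene-dense regions does not account for all of it, because genes over 100 kb in the most gene-dense part of the genome (the upper 25% of genes by number of neighbours) were at 1.05 (SD 0.0360), with no V5 library reaching the lowest V5 value of the short genes, and short genes in the least gene-dense 25% were still at 1.13 (SD 0.0867) with the groups apart, but the excess was larger, at 1.28 (SD 0.134), in the most gene-dense 25%, so a part of it may go with density. A few highly counted genes stay open. Without the 200 short genes of highest mean share the ratio was 1.13 (SD 0.103), with V5 replicate 1 at 1.03 and every V5 library still above every wild-type library. Without the 200 chosen by their highest single library it was 1.10 (SD 0.0963), with V5 replicate 1 at 0.991, below every wild-type library (exact permutation p = 0.4). Both choices used the counts that are compared. The latter takes out high values of the most variable libraries, so that overlap cannot settle the question. Tagged MOZ near active genes is a candidate explanation, since the excess was 1.22 in short coding genes and 1.02 in silent receptor genes of like length, but the receptors are not a neutral control, as their share was 1.91 times the input's in V5 and 1.88 times in wild type (coding genes, 0.953 and 0.784), and short lncRNA genes were at 1.06 with the groups overlapping. A loss of short genes from the wild-type libraries stays open beside it, as the values go both ways: over all short genes the V5 share was 0.976 of the input's and the wild-type share 0.823 of it, but in the least gene-dense 25% the wild-type share was 0.991 of the input's and V5 was at 1.12 (SD 0.0859), with 1.05 as its lowest library; with 1 input, no promoter counts and no genome sequence used here, local base composition at short coding genes was not examined.

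V5 replicates 1 and 2 varied more than the other libraries, with estimated library weights of 0.733 and 0.648, although V5 replicate 3, at 0.884, was also below the 1.30 to 1.40 of wild type. Depth alone does not account for this: with every library thinned to 800000 reads, the chi-square per degree of freedom between V5 replicates 1 and 2 was 8.81, 2.53 times that of the most different wild-type pair. In the silent receptor genes that ratio was still 1.92, which argues against binding of MOZ as the whole cause if those genes are unbound. They are not a neutral control, as above, and their counts are uncertain, so this argument is weak. Repeated counting of few DNA fragments could account for the larger spread. The ratio was at least 1.71 in each of 5 gene classes, which overlap, as 1 of them is all genes. The thinned V5 replicates 1 and 2 had 7930 and 8131 genes at 0, against 5689 to 7077 in wild type. A larger spread of another origin could also give such values, so they do not single out repeated counting. Reads themselves, which would show duplicates, were not analysed here.

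Some Skint genes of chromosome 4, a family of selection proteins of epidermal T cells, were low in V5 replicate 3, with Skint5 at 0.492 of the wild-type mean, while Skint7, Skint8 and Skint11 were inside the wild-type range at 0.875, 0.609 and 0.901 of its mean, and in Skint1, Skint2, Skint8 and Skint11 V5 replicate 1 was lower than replicate 3. Skint4, Skint3 and Skint9, between 112072016 and 112433985, held 34.4 CPM together in that library, 157 and 148 in V5 replicates 1 and 2, 203 to 249 in the wild-type libraries and 465 in the input. The V5 replicate 3 value was 0.147 of the wild-type mean, and counting error does not account for it, since its exact Poisson interval ended at 0.177. A difference in copy number between embryos may be the source but stays open, because Skint6, beyond the adjoining genes, was at 0.256, and the adjoining Skint genes on both sides were below wild type (175 to 206 CPM) in all 3 V5 libraries, with 121, 155 and 146 CPM in replicates 1 to 3, so that their level does not set replicate 3 apart. The family has near-identical members, so reads may also have been shared among them.

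Chance was examined by regrouping. The 6 ChIP libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 splits gave 0 genes past the threshold, so the highest of the others was 0. At an unadjusted p under 0.05 the real split had 600 genes and 4 of the 10 splits had as many, the highest of the others having 804, with V5 replicates 1 and 2 and wild-type replicate 2 on one side. For gene lists past the threshold, 2 of the 10 splits gave as many as the real one, which had 1, and the highest of the others also had 1.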
